A study of Mus musculus with 18 samples.

How the data were processed

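Nuclear RNA was measured in livers of female HEP-INTACT mice, a line in which hepatocyte nuclei carry a tag and can be pulled from a suspension of liver nuclei by immunoprecipitation (IP). Per the labels and the series' design text, 6 mice were used, 3 fed ad libitum and 3 fasted for 16 h from zeitgeber time 12, the start of the dark phase. From each mouse came 3 libraries, namely the IP of fresh liver, the supernatant left after that IP, and the IP of frozen liver. The 18 libraries form 6 groups of 3, and replicates are separate mice.

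Per the labels' protocols, nuclei went into Trizol and RNA was purified on columns with DNase digestion. Libraries were made from 50 to 100 ng of total RNA with a stranded kit and no poly-A selection, and sequenced as 50 bp paired reads. Unspliced transcripts are therefore part of the signal. STAR 2.4.2a, DESeq2 1.24.0 and the mm10 build were used by the authors, per the submitters' processing notes, which as used here do not give the role of each. The counting tool and its strand setting were not given in the sources used here, so a gene and an overlapping antisense partner, and near-identical paralogs such as the Cyp2c, Cyp4a, Sult2a and Lilr families, are uncertain.

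The authors deposited raw counts per gene, whole numbers that were not normalized, for 20105 genes, each with a RefSeq accession. The length given for each gene in the deposited table equals the distance from its start to its end in all 20105 genes, introns included, so the feature counted appears to be the whole transcribed region. The coordinates overlapped those of the RefSeq table of the same build for 99.7% of 19121 genes found there once. The table holds 0 rows for ribosomal, small nuclear, microRNA or mitochondrially encoded transcripts, so leaving out small RNA genes had nothing to remove and was not run, and the list of mitochondrially encoded genes had no members to test. A further 6 columns of the count table, named as supernatant of frozen liver, match no sample and were used in no step. The authors also deposited a table of their own comparisons with log2 fold changes and adjusted p-values for fasting in fresh and frozen IP, and normalized counts, which are the raw counts divided by 1 factor per library (signal in linear units). That table was used only where it is named. Total counts ran from 13828945 to 54434263 per library, and the 10 most abundant genes took 5.37 to 8.13% of them. Within groups, chi-square per gene between libraries was 16.7 or more, so no library was counted as a duplicate.

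Column letters A, B and C number the libraries of a group in the count table and stand in no label, so columns were assigned to groups only. Whether letters pair libraries of 1 mouse was checked before any fit, on deviations of log2 CPM (prior count 2) from group means over genes with a mean of at least 3. Libraries with the same letter correlated at 0.555 to 0.902 between fresh and frozen IP and at 0.152 to 0.437 between IP and supernatant. Libraries with different letters correlated at -0.586 to 0.010. The letter within a feeding state therefore served as the block of a paired alternative.

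Each of 7 comparisons was tested with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3 on the counts, with TMM scaling, filterByExpr by group and Benjamini-Hochberg adjusted p under 0.05. They were fasting in fresh IP, frozen IP and supernatant, frozen minus fresh IP, IP minus supernatant in fresh liver, and the differences of the fasting response between preparations and between fractions. A comparison used only its own groups, with no block. Log2 fold changes are from edgeR and are given with the SE of the difference of group means of log2 CPM (prior count 2). This SE takes libraries as independent. In comparisons that share mice it leaves out the pairing and does not measure the spread of differences within mice. CPM are given as mean ± SD over n = 3 libraries, scaled over all 18. A positive value is higher in fasted, frozen or IP. Gene locations are on mm10, 1-based.

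There were 24 gene lists fixed before the data were examined, covering gluconeogenesis, fatty acid oxidation and ketogenesis, fatty acid synthesis and glycolysis, cholesterol synthesis, insulin and IGF signalling, glucocorticoid-responsive genes, the circadian clock, bile acids, the urea cycle and amino acid catabolism, the unfolded protein response, autophagy and lysosome, acute phase, immediate early genes, heat shock, xenobiotic metabolism, cell cycle, mitochondrially encoded genes, and markers of hepatocytes, endothelial cells, Kupffer cells and macrophages, stellate cells and fibroblasts, cholangiocytes, lymphocytes, and neutrophils and erythroid cells. Some genes stand in 2 lists, such as Per1 and Gadd45b. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated from the residuals, and with fry. Camera asks whether a list stands apart from other genes, and fry whether its genes change at all. Fry results are mostly given as counts of lists, with the other alternatives. Members past the threshold are counted over all genes tested and adjusted over the list alone.

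The rule for named genes was fixed too. It takes the 8 highest and 8 lowest log2 fold changes in fasting in fresh IP, frozen minus fresh IP and IP minus supernatant, and 5 each way in the other comparisons, among genes past the threshold with a mean logCPM of at least 3. Outside the 2 differences of responses, the libraries of the 2 sides had also to be separate. Provisional gene names and small RNA genes were left out of these. From each list it takes the 3 members with the largest change among those past the threshold, or the 2 most abundant where none passed. Genes named for fasting in fresh IP may return in other fasting comparisons, and Sun1 and Alb are named throughout as checks.

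The alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of CPM of at least 1 in 3 libraries, 1 fit of all 18 libraries, the mouse as a block where mice are shared, an added fold threshold of 2, and leaving out each library in turn. A few more were chosen after seeing the data and are named as such where they appear. In simulated counts with 200 changed genes, 2-fold changes were recovered in 61.2% for fasting in fresh IP, 65.7% in frozen IP, 73.1% in supernatant, 88.1% for frozen minus fresh IP and 86.6% for IP minus supernatant, but in 16.4 and 23.9% for the differences of responses between preparations and between fractions, where 4-fold changes were recovered in 69.7 and 83.3%. For fasting in fresh IP, 13 of 117 simulated calls were false. With a simulated mouse effect and the mouse as a block, 2-fold changes were recovered in 91.0% for frozen minus fresh IP, 92.5% for IP minus supernatant, 83.6% for the difference between preparations and 34.3% for that between fractions, with 17 of 192, 8 of 175, 20 of 165 and 4 of 81 calls false.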

Results

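The series holds RNA-seq counts of hepatocyte nuclei pulled down from fresh and from frozen liver, and of the nuclei left in the supernatant, in fed and fasted female mice. Each of the 6 groups has 3 libraries, from 3 mice. Total counts per library were 25675086 to 54166985 in fresh IP of fed mice and 33242961 to 54434263 in fresh IP of fasted mice. They were 28315372 to 34770217 in supernatant of fed mice and 34247281 to 37188834 in that of fasted mice. Frozen IP had 13828945 to 49027343 in fed and 41178186 to 43814180 in fasted mice.

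The comparison of IP with supernatant asks which transcripts the pull-down enriches. All 21 hepatocyte markers were higher in IP, with a median log2 difference of 4.39, and so were all 20 genes of the urea cycle and amino acid catabolism and all 15 of bile acid synthesis and transport. Alb, which encodes serum albumin, was at 2258 ± 78.2 CPM in fresh IP of fed mice and at 243 ± 128 CPM in their supernatant (SD, n = 3), and its averaged difference was 3.10 ± 0.22 (SE). Cps1, the first enzyme of the urea cycle, differed by 5.35 ± 0.26. All 19 endothelial, 17 Kupffer cell and macrophage, 16 stellate cell and fibroblast, and 19 lymphocyte markers were lower in IP. Adgre1, a macrophage receptor, was at 1285 ± 295 CPM in supernatant of fed mice and at 1.47 ± 0.63 in their IP (-9.54 ± 0.19). Bank1 of the lymphocyte list differed by -8.98 ± 0.22, Pecam1 of endothelium by -6.36 ± 0.21 and Pdgfrb of stellate cells by -4.29 ± 0.24.

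In all, 12181 of 14322 genes passed the edgeR test, 6016 higher and 6165 lower in IP. Among the genes named by size, Sult2a2 (6.12 ± 0.60), Golt1a (6.06 ± 0.31), the xenobiotic receptor Nr1i3 (6.06 ± 0.15) and Cyp4a32 (5.93 ± 0.20) were higher in IP, and Hpgds (-9.99 ± 0.14), Kcnj16 (-9.99 ± 0.13) and the immune receptor Lilrb4a (-9.86 ± 0.13) were lower. Sun1, of the nuclear envelope, was 1.83 ± 0.14 higher. Cholangiocyte markers went both ways, 4 higher and 2 lower of 7. Of 16 cell cycle genes 14 were lower in IP, among them Mki67 (-5.19 ± 0.23), and of 22 immediate early genes 13 were lower, among them Fos (-4.74 ± 0.50), and 3 higher. Of 6 neutrophil and erythroid markers 5 were lower, among them Csf3r (-9.25 ± 0.22).

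The metabolic lists were mostly higher in IP. These were gluconeogenesis (14 of 14), fatty acid oxidation and ketogenesis (29 of 30), fatty acid synthesis and glycolysis (18 of 21), cholesterol synthesis (24 of 24), insulin and IGF signalling (12 of 15), xenobiotic metabolism (18 of 19), the circadian clock (16 of 18), acute phase (16 of 19), heat shock (12 of 14) and the unfolded protein response (12 of 19). Of autophagy and lysosome genes 8 were higher and 5 lower of 18, and of glucocorticoid-responsive genes 7 were higher and 1 lower of 15. The counts adjusted over the list alone were the same for all 23 lists with members. Directional fry called all 23. By camera 18 lists stood apart from other genes. None held with an estimated correlation, where the adjusted p ran from 0.0716 for bile acid genes to 0.423 for cholesterol synthesis and was 0.145 for hepatocyte, 0.323 for endothelial, 0.223 for Kupffer cell, 0.321 for stellate cell and 0.238 for lymphocyte markers. With the mouse as a block the calls of the unfolded protein response (adjusted p = 0.0774) and of neutrophil and erythroid markers (adjusted p = 0.0525) ended while that of heat shock was gained (adjusted p = 0.0314, and without a block adjusted p = 0.482 with an estimated correlation).

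**Figure D1:**
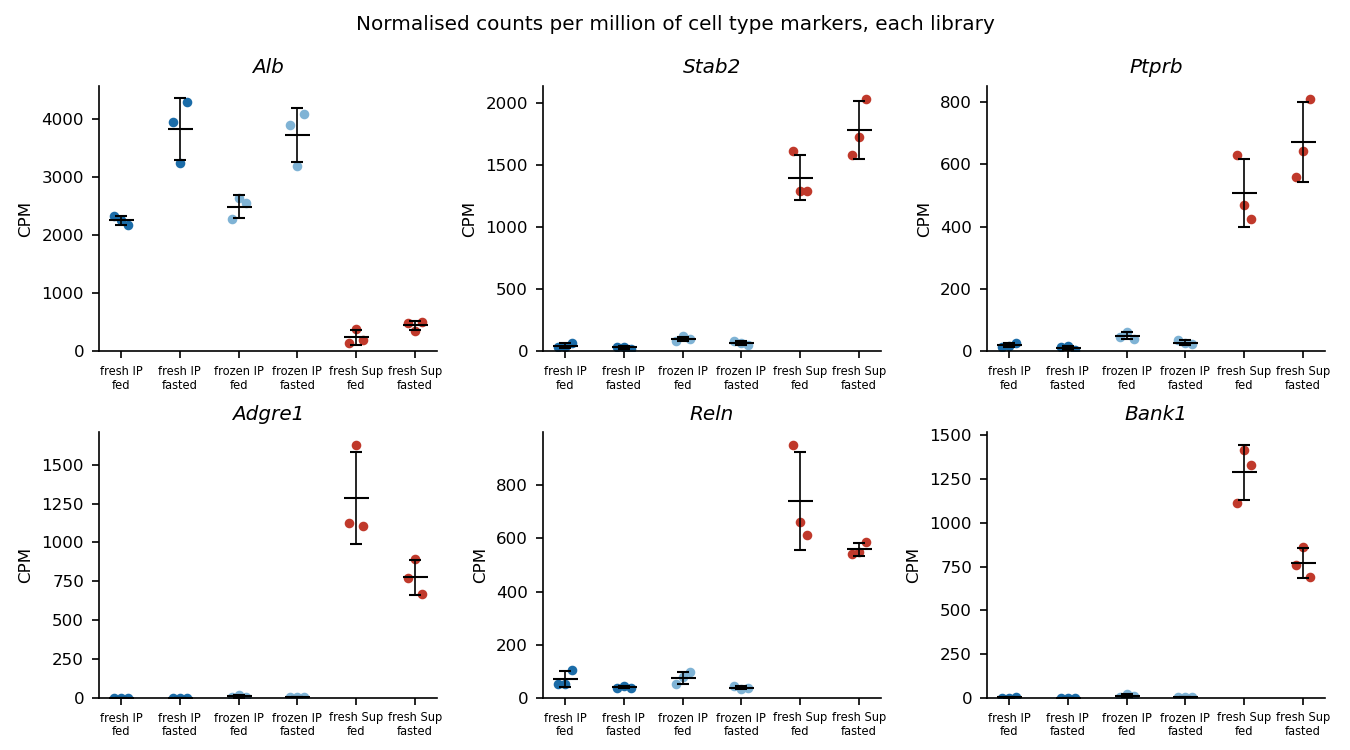
Normalised CPM (linear axes from 0) of the hepatocyte gene Alb, the endothelial genes Stab2 and Ptprb, the macrophage gene Adgre1, the stellate cell gene Reln and Bank1 of the lymphocyte list in each of the 18 libraries (points), with the mean and SD of each group of 3 (bars). Alb is highest in IP, and the other 5 genes are highest in supernatant.

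Fasting in fresh IP asks how hepatocyte transcription responds to 16 h without food. Of 30 genes of fatty acid oxidation and ketogenesis 26 rose and none fell. Acot1, an acyl-CoA thioesterase (chromosome 12, 84009502 to 84017669), rose from 1.81 ± 0.65 to 59.6 ± 9.89 CPM (SD, n = 3), a log2 change of 5.11 ± 0.30 (SE). Cyp4a14, a fatty acid hydroxylase, rose by 4.57 ± 0.29, the hormone gene Fgf21 by 5.03 ± 0.57 and the lipid droplet gene Cidec by 5.88 ± 0.47. Cholesterol synthesis went the other way, with 21 of 24 genes lower, among them Mvd (-4.43 ± 0.49), Fdps (-4.14 ± 0.55) and Insig1 (-3.87 ± 0.66), and in fatty acid synthesis and glycolysis 14 of 21 fell, among them Pnpla3 (-6.94 ± 1.02), Thrsp (-6.20 ± 0.96) and the desaturase Scd1 (-4.83 ± 1.02).

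The same counts adjusted over the list alone were 26 higher for fatty acid oxidation, 23 lower for cholesterol synthesis, and 2 higher and 17 lower for fatty acid synthesis. Camera called these lists (adjusted p = 4.42e-35, 5.28e-29 and 2.29e-09). With an estimated correlation the adjusted p was 0.167, 0.184 and 0.362. By directional fry it was 0.00848, 0.00848 and 0.0507.

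Among glucocorticoid-responsive genes 7 rose and 2 fell of 15 (9 and 2 adjusted over the list alone), with the cell cycle inhibitor Cdkn1a at 4.54 ± 0.71, Gadd45b at 4.55 ± 0.50 and Per1 at 3.35 ± 0.70. Of 18 clock genes 9 fell and 1, Per1, rose (10 and 2 adjusted over the list alone), and Dbp, a clock output gene, fell from 17.3 ± 1.18 to 0.80 ± 0.19 CPM (-4.39 ± 0.20). In xenobiotic metabolism 10 fell and 4 rose of 19 (13 and 4 adjusted over the list alone), among them Cyp1a2 (-2.97 ± 0.34) and Cyp2a5 (-2.83 ± 0.18). Bile acid genes fell in 7 of 15 with 1 higher, the same adjusted over the list alone, including Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-2.28 ± 0.55), while the phospholipid transporter Abcb4 rose (1.36 ± 0.24). For these 4 lists camera gave adjusted p = 2.35e-05, 4.01e-07, 3.77e-06 and 0.0225, and with an estimated correlation the adjusted p was 0.167, 0.167, 0.167 and 0.362.

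Heat shock genes rose in 7 of 14 (9 adjusted over the list alone) and immediate early genes in 6 of 20 (6 adjusted over the list alone), and 3 of 14 gluconeogenesis genes rose and 1 fell, likewise over the list alone, with Ppargc1a at 1.95 ± 0.27, Ldha at 1.45 ± 0.21 and the glycerol kinase Gk at 1.41 ± 0.09. Their camera adjusted p of 0.00112, 0.0134 and 0.0256 became adjusted p = 0.573, 0.573 and 0.699 with an estimated correlation. Over the gluconeogenesis list, whose median fasting change was 0.367, fed library C lay at -0.927 from the other 2 fed libraries. Insulin and IGF signalling had 4 genes higher and 4 lower of 15 (4 and 5 adjusted over the list alone), with Foxo1 at 1.41 ± 0.30. The urea cycle list had 2 higher and 4 lower of 20, the same over the list alone, with Otc at -1.49 ± 0.35, the unfolded protein response 2 and 5 of 18 (3 and 5 adjusted over the list alone), with Pdia4 at -0.85 ± 0.13, acute phase 1 and 5 of 18 (2 and 6 adjusted over the list alone), with Hp at 1.30 ± 0.26, and autophagy 1 and 1 of 18 (0 and 1 adjusted over the list alone), with Fnip2 at -1.28 ± 0.27. None of these 5 lists was called.

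Members of the cell type lists moved in part. Endothelial markers fell in 3 of 19 (1 adjusted over the list alone), among them Fcgr2b (-1.68 ± 0.39). Camera gave adjusted p = 0.0451, and adjusted p = 0.81 with an estimated correlation. All 19 are lower in IP than in supernatant, and carry-over was not told apart from a fasting response here. Kupffer cell markers rose in 2 of 13, among them Fcer1g (1.34 ± 0.20), and stellate markers fell in 2 of 14, among them Col3a1 (-1.77 ± 0.33). Fcer1g was scarce, at 0.92 ± 0.19 CPM in fed and 2.34 ± 0.33 in fasted mice. In the authors' deposited table its change was 1.24 in fresh IP and 0.46 in frozen IP (adjusted p = 0.0816 in frozen IP). For these markers too, carry-over was not told apart from a fasting response. Cell cycle genes fell in 3 of 12 (4 adjusted over the list alone), among them Mki67 (-2.91 ± 0.35) and Top2a (-2.66 ± 0.36). Of hepatocyte markers 3 rose and 3 fell of 21, and Alb rose by 0.78 ± 0.12. Pkhd1 of the cholangiocyte list fell (-1.33 ± 0.10), 1 of 6, Cd247 of the lymphocyte list rose (2.47 ± 0.52), 1 of 8, and Alas2 of the erythroid list fell (-1.67 ± 0.19), 1 of 2, though Pkhd1 and Alas2 are higher in IP than in supernatant. Counts adjusted over the list alone were the same for the Kupffer cell, stellate cell, hepatocyte, cholangiocyte, lymphocyte and erythroid lists. Sun1 was at 0.49 ± 0.29 (adjusted p = 0.159).

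Outside the lists, the receptor gene Lepr (5.10 ± 1.06), Slc41a3 (4.41 ± 0.41) and Plin4 (4.22 ± 0.37) rose, and Chrna4 (-9.14 ± 1.13), A1bg (-6.77 ± 0.52) and Slc22a26 (-4.90 ± 0.82) fell. Without genes that are higher in supernatant than in IP, a choice made after seeing the data, 2256 genes passed, 1213 higher and 1043 lower in fasted. In all, 3145 of 12548 genes passed, 1559 higher and 1586 lower in fasted. The count was 2050 without fed library A, 1943 without fed B and 1429 without fasted A, and of 67 named calls 24 ended without some library, 20 of them without fasted A, among these Alb (0.75, adjusted p = 0.0509).

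**Figure D2:**
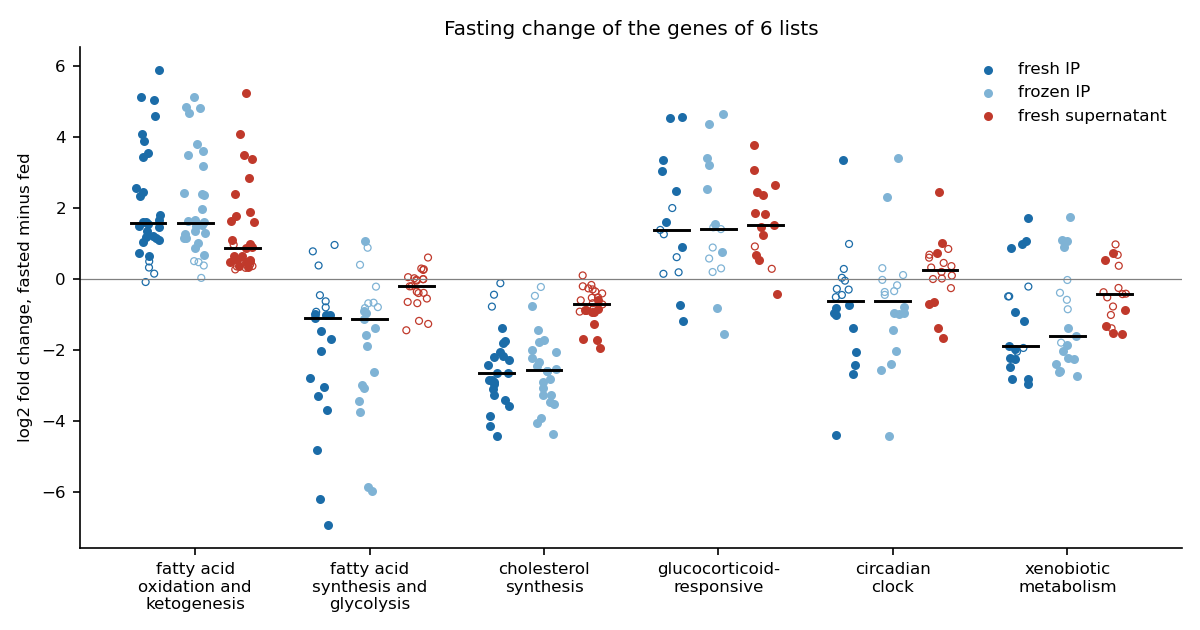
Log2 fold change, fasted minus fed, of each tested member of 6 gene lists (points) in fresh IP, frozen IP and supernatant, with the median of each list (bars). Filled points passed the edgeR threshold. The median of cholesterol synthesis is -2.66 in fresh IP, -2.58 in frozen IP and -0.71 in supernatant.

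Fasting in frozen IP asks the same of frozen tissue of the same mice. Acot1 rose by 4.84 ± 0.19, Cyp4a14 by 4.67 ± 0.35, Fgf21 by 4.82 ± 0.51, Lepr by 4.78 ± 1.05 and Cdkn1a by 4.37 ± 0.66. Chrna4 (-7.88 ± 0.56), A1bg (-6.59 ± 0.49), Pnpla3 (-5.99 ± 0.83), Thrsp (-5.87 ± 0.83), Mvd (-4.37 ± 0.47) and Dbp (-4.44 ± 0.38) fell. Fatty acid oxidation rose in 26 of 30 genes (26 adjusted over the list alone), cholesterol synthesis fell in 22 of 24 (23 adjusted over the list alone), and fatty acid synthesis fell in 13 of 21 and rose in 1 (14 and 1 adjusted over the list alone). Camera called 12 lists, and with an estimated correlation none held, with adjusted p = 0.108, 0.132 and 0.256 for these 3. Gluconeogenesis (3 higher and 1 lower of 14), bile acid (1 and 7 of 15), immediate early (6 and 1 of 20) and heat shock genes (5 and 0 of 14) were called too, with adjusted p = 0.554, 0.295, 0.408 and 0.408 with an estimated correlation. Adjusted over the list alone these were 4 and 1, 1 and 8, 7 and 1, and 10 and 0.

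Glucocorticoid-responsive genes rose in 7 and fell in 2 of 15, the clock rose in 2 and fell in 9 of 18, with Per3 at -2.58 ± 0.15, and xenobiotic genes rose in 4 and fell in 10 of 19, with Cyp1a2 at -2.75 ± 0.22. Adjusted over the list alone the counts were 9 and 2, 2 and 9, and 4 and 13, and with an estimated correlation the adjusted p was 0.212, 0.0803 and 0.0803. Endothelial markers fell in 8 of 19 and rose in 1 (13 and 1 adjusted over the list alone), with Fcgr2b at -1.30 ± 0.08. Stellate markers fell in 6 of 15 (7 adjusted over the list alone), with Col3a1 at -2.20 ± 0.32. With an estimated correlation the adjusted p was 0.465 and 0.257. In supernatant the median fasting change of these 2 lists was 0.402 and -0.261. The rise of endothelial markers from fresh to frozen IP, as a share of their gap to supernatant, had a median of 5.97% in fed and 2.41% in fasted mice. Unequal carry-over and a fasting response were therefore not told apart for these markers.

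Without genes that are higher in supernatant than in IP, a choice made after seeing the data, 2050 genes passed, 1117 higher and 933 lower. In all, 2918 of 12926 genes passed, 1421 higher and 1497 lower. The count was 1168 without fasted library A, 1885 without fasted B and 1810 without fasted C, and of 76 named calls 27 ended without some library, 22 of them without fasted A, among these Per1 (3.40 ± 1.07, and 3.27 without fasted A, adjusted p = 0.052).

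The 2 fasting responses were then set side by side. Over the 12472 genes tested in both, 1181 rose in both preparations, of 1554 in fresh and 1412 in frozen IP, where independent lists would share 175.9, and 1216 fell in both, of 1576 and 1478, where independent lists would share 186.8. No gene passed in both in opposite directions. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.947 (jackknife SE over mice 0.035). Both responses come from the same mice, and of the covariance of 0.549, the part expected from shared mice was 0.051, and over 36 splits that took different mice for each preparation it was 0.499 on average. The authors' deposited table gives 4879 genes at adjusted p under 0.05 in fresh and 5032 in frozen IP, and of the genes called here, 3080 of 3145 and 2880 of 2918 pass in the authors' deposited table too, all in the same direction.

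**Figure D3:**
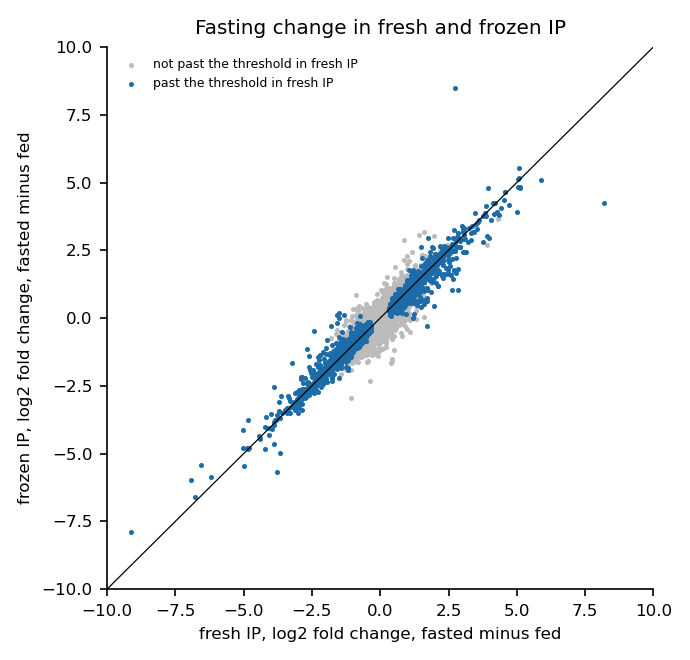
Log2 fold change, fasted minus fed, in fresh IP (horizontal) and frozen IP (vertical) for 12472 genes tested in both, with the line of equality. Blue points passed the threshold in fresh IP, and their r is 0.984.

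The difference of the response between preparations was tested itself. By edgeR 0 of 13162 genes passed, and DESeq2 and the fit with the mouse as a block also gave 0. By edgeR without a block 43 genes had an unadjusted p under 0.05. That is far below the share of 0.05 expected where nothing differs. This fit leaves out the mouse that fresh and frozen libraries share, so the 43 does not measure how alike the responses are. Pnpla3 differed by 0.95 ± 1.32, Acot1 by -0.27 ± 0.36 and Mvd by 0.06 ± 0.68 (SE without pairing by mouse). In simulated counts, 2-fold differences of response were recovered in 16.4% of genes without a block and in 83.6% with one. The 2 shares come from separate simulated counts, and only the blocked ones held a mouse effect. Their gap therefore does not measure what a block gains on the same counts. Of the lists, the Kupffer cell (median -0.62) and stellate cell (median -0.28) markers had a lower fasting change in frozen than in fresh IP by camera (adjusted p = 0.00112 and 0.00657), with adjusted p = 0.95 for both with an estimated correlation and 0 members past the threshold, over all genes or adjusted over the list alone. Fed library B of frozen IP lay 1.35 above the other fed frozen libraries in Kupffer cell markers, and without it, a choice made after seeing the data, neither list was called (medians 0.19 and -0.13, adjusted p = 0.533 and 0.196). Without both fed B libraries the Kupffer cell list was called (median -0.28, adjusted p = 3.96e-08, and adjusted p = 0.154 with an estimated correlation) and the stellate cell list was not (adjusted p = 0.236). With the mouse as a block both were called (adjusted p = 4.65e-05 and 0.0346). In that fit fatty acid synthesis (up, adjusted p = 9e-05) and the urea cycle (down, adjusted p = 0.0171) were called as well, and without a block an estimated correlation gave adjusted p = 0.95 for both.

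Frozen against fresh IP asks what the tissue preparation changes in hepatocyte nuclei. Endothelial markers were higher in frozen IP in 17 of 19 genes, Kupffer cell and macrophage markers in 9 of 17, lymphocyte markers in 5 of 12, stellate cell markers in 3 of 15, cholangiocyte markers in 1 of 9 and neutrophil and erythroid markers in 1 of 2. Adgre1 rose from 1.47 ± 0.63 CPM in fresh to 9.62 ± 7.07 in frozen IP of fed mice and from 1.36 ± 0.06 to 5.72 ± 0.09 in fasted mice (2.42 ± 0.33), against 1285 ± 295 and 777 ± 113 CPM in the supernatants. Pecam1 rose by 1.58 ± 0.19, Vsig4 of Kupffer cells by 2.45 ± 0.40, Bank1 by 2.09 ± 0.36, Col1a1 by 1.79 ± 0.27 and the neutrophil gene Csf3r by 1.99 ± 0.38. Of the hepatocyte markers 0 of 21 passed by edgeR (Alb 0.08 ± 0.09, Cps1 -0.13 ± 0.23), with a median of -0.09.

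Adjusted over the list alone, 19 endothelial, 10 Kupffer cell, 7 lymphocyte, 3 stellate, 3 cholangiocyte and 1 neutrophil and erythroid genes passed. Camera called the first 5 (adjusted p = 1.33e-34, 1.6e-18, 2.79e-14, 0.0317 and 0.003), and with an estimated correlation the adjusted p was 0.0665, 0.11, 0.0665, 0.671 and 0.288. In the lists not named here no member passed except Atf4 of the unfolded protein response (-0.44 ± 0.12), whose call ended without fed A or B or fasted A or B of fresh IP or fasted B or C of frozen IP (adjusted p = 0.0628 to 0.0935). With the mouse as a block, bile acid (adjusted p = 0.0141), xenobiotic (adjusted p = 0.0313) and hepatocyte genes (adjusted p = 0.0444) were called lower, and without a block an estimated correlation gave adjusted p = 0.671, 0.671 and 0.657.

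In all, 621 genes were higher and 58 lower in frozen IP of 13162. Among the genes named by size were Slc8a1 (2.42 ± 0.22; chromosome 17, 81373105 to 81738387), Hdac9 (2.24 ± 0.31), the leukocyte gene Dock2 (1.94 ± 0.28), Arhgap15 (1.85 ± 0.31) and Fli1 (1.64 ± 0.23), against Ncapd2 (-0.75 ± 0.15), Epm2aip1 (-0.62 ± 0.09), Pigm (-0.60 ± 0.06), Phb2 (-0.57 ± 0.08) and Dnajc22 (-0.54 ± 0.08). With the mouse as a block 2168 genes passed, 1238 higher and 930 lower, all 679 among them. The count was 409 without fed library A of fresh IP and 442 without fasted A of frozen IP, of 31 named calls 5 ended without some library, and without genes that are higher in supernatant than in IP, a choice made after seeing the data, the count was 66, of which 20 were higher and 46 lower.

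Fasting in supernatant asks how the remaining nuclei respond. Fatty acid oxidation and ketogenesis rose in 23 of 29 genes (28 adjusted over the list alone; camera adjusted p = 5.99e-47, adjusted p = 0.0312 with an estimated correlation), led by Cyp4a14, from 4.21 ± 0.49 to 70.3 ± 0.67 CPM (SD, n = 3; 4.07 ± 0.09, SE), and Cyp4a10 (3.38 ± 0.25). Glucocorticoid-responsive genes rose in 12 of 15 and fell in 1 (13 and 1 adjusted over the list alone), with the chaperone gene Fkbp5 at 3.06 ± 0.26, Ddit4 at 3.76 ± 0.79 and the metallothionein Mt2 at 2.65 ± 0.29. Cholesterol synthesis fell in 10 of 24 (20 adjusted over the list alone), with Sqle at -1.94 ± 0.28, and cell cycle genes fell in 6 of 16 (10 adjusted over the list alone), with Ccne2 at -2.31 ± 0.20 and Mcm5 at -1.68 ± 0.12. Camera gave adjusted p = 1.69e-24, 1.53e-14 and 6.62e-13 for these 3, and with an estimated correlation the adjusted p was 0.143, 0.263 and 0.263.

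Over the gluconeogenesis list, whose median fasting change was 0.564, fed library C lay at -0.502 from the other 2 fed libraries. Gluconeogenesis genes rose in 6 of 14, with Ppargc1a at 1.33 ± 0.32 and Pck1 at 1.81 ± 0.53, and immediate early genes in 5 of 22, with Fosl2 at 1.99 ± 0.29. Adjusted over the list alone these were 6 and 8 higher, with 1 immediate early gene lower, and with an estimated correlation the adjusted p was 0.627 and 0.551. Of 21 genes of fatty acid synthesis 0 passed by edgeR (0 higher and 4 lower adjusted over the list alone), with Acaca at -0.02 ± 0.09. In the clock 3 rose and 4 fell of 18 (6 and 4 adjusted over the list alone), with Nr1d1 at -1.68 ± 0.25 and Dbp at -1.40 ± 0.24. Insulin and IGF signalling had 4 higher and 1 lower of 15 (5 and 1 adjusted over the list alone), with Irs2 at 1.08 ± 0.20. Xenobiotic genes had 2 higher and 4 lower of 17 (3 and 7 adjusted over the list alone), acute phase had 1 higher of 17, Hp (1.59 ± 0.31), the same adjusted over the list alone, and autophagy rose in 3 of 18 (6, with 1 lower, adjusted over the list alone). These 3 were called by camera, with adjusted p = 0.551, 0.668 and 0.263 with an estimated correlation.

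Hepatocyte markers had a median of 0.43 with 2 higher and 1 lower of 21 (4 and 1 adjusted over the list alone), and Alb was at 0.90 ± 0.44 (adjusted p = 0.159). Endothelial markers rose in 2 of 19, the same adjusted over the list alone, with Lyve1 at 2.37 ± 0.58, and stellate markers rose in 1 and fell in 2 of 16 (1 and 5 adjusted over the list alone), with Col3a1 at -1.32 ± 0.15. Kupffer cell markers rose in 1 of 17 (1 higher and 1 lower adjusted over the list alone). Camera called the hepatocyte and endothelial lists up and the stellate list down (adjusted p = 0.00307, 0.00115 and 0.0356), with adjusted p = 0.695, 0.678 and 0.695 with an estimated correlation. Of 6 neutrophil and erythroid markers 0 passed (1 higher adjusted over the list alone), with a median of 0.70, and camera called them up (adjusted p = 0.0356, adjusted p = 0.551 with an estimated correlation). Outside the lists, Tgfb3 (2.93 ± 0.23) and Lepr (2.71 ± 0.31) rose, and A1bg (-3.41 ± 0.53) and Dscaml1 (-2.49 ± 0.30) fell.

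In all, 866 of 13921 genes passed, 471 higher and 395 lower, and 1871 by DESeq2. The count was 316 and 327 without fed libraries B and C and 197, 541 and 473 without fasted A, B and C, and of 63 named calls 44 ended without some library. Without fed B, fed C or fasted A the adjusted p was 0.0653, 0.0588 and 0.0601 for Ddit4, 0.116, 0.0777 and 0.111 for Pck1 (0.0522 and 0.0899 without fasted B and C), 0.0988, 0.103 and 0.0871 for Ppargc1a (0.0577 without fed A) and 0.0521, 0.0571 and 0.0633 for Irs2. It was 0.0547, 0.101 and 0.104 for Lyve1 without fed A, B and C, 0.0586 and 0.0591 for Hp without fed C and fasted A, and 0.0527 for Dbp without fed B.

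The difference of the fasting response between IP and supernatant was tested itself. Cholesterol synthesis fell more in IP in 14 of 24 genes (18 adjusted over the list alone), with Mvd differing by -3.53 ± 0.53 and Fdps by -2.90 ± 0.65, and fatty acid synthesis in 9 of 21 (14 adjusted over the list alone), with Pnpla3 at -6.96 ± 1.06. In supernatant Pnpla3 was at 9.67 ± 2.57 CPM in fed and 9.37 ± 1.87 in fasted mice, against 148 ± 137 and 1.19 ± 0.59 in IP. Fatty acid oxidation rose more in IP in 9 of 30 (11 adjusted over the list alone), with Acot1 at 3.18 ± 0.38 and Acot2 at 3.12 ± 0.28. In the clock 8 of 18 genes fell more or rose less in IP (9 adjusted over the list alone), with Dbp at -3.04 ± 0.33. Camera also called hepatocyte markers (median -0.548), endothelial markers (median -1.13) and acute phase (median -0.667) down, and heat shock (median 0.5) up. With an estimated correlation the adjusted p of these was 0.696, 0.569, 0.569 and 0.569.

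Slc41a3 rose from 1.55 ± 0.25 to 32.6 ± 14.3 CPM in IP and was at 15.4 ± 1.31 and 15.7 ± 2.48 in supernatant (4.33 ± 0.45), and Gadd45b (4.21 ± 0.57) and Cdkn1a (3.03 ± 0.77) also rose more in IP. Ddit4, an inhibitor of growth signalling, went the other way (-5.00 ± 0.84). Genes past the threshold in both fractions numbered 152 higher in both (49.8 for independent lists), 125 lower in both (39.8) and 46 with opposite directions. Both fractions come from the same mice, and the number that shared mice alone would give was not computed. In all, 1367 of 14322 genes passed, 532 higher and 835 lower, and 2307 by DESeq2. The count was 793 without fasted library A of IP, 816 and 852 without fed C and fasted C of supernatant and 771 without fasted A of supernatant.

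**Figure D4:**
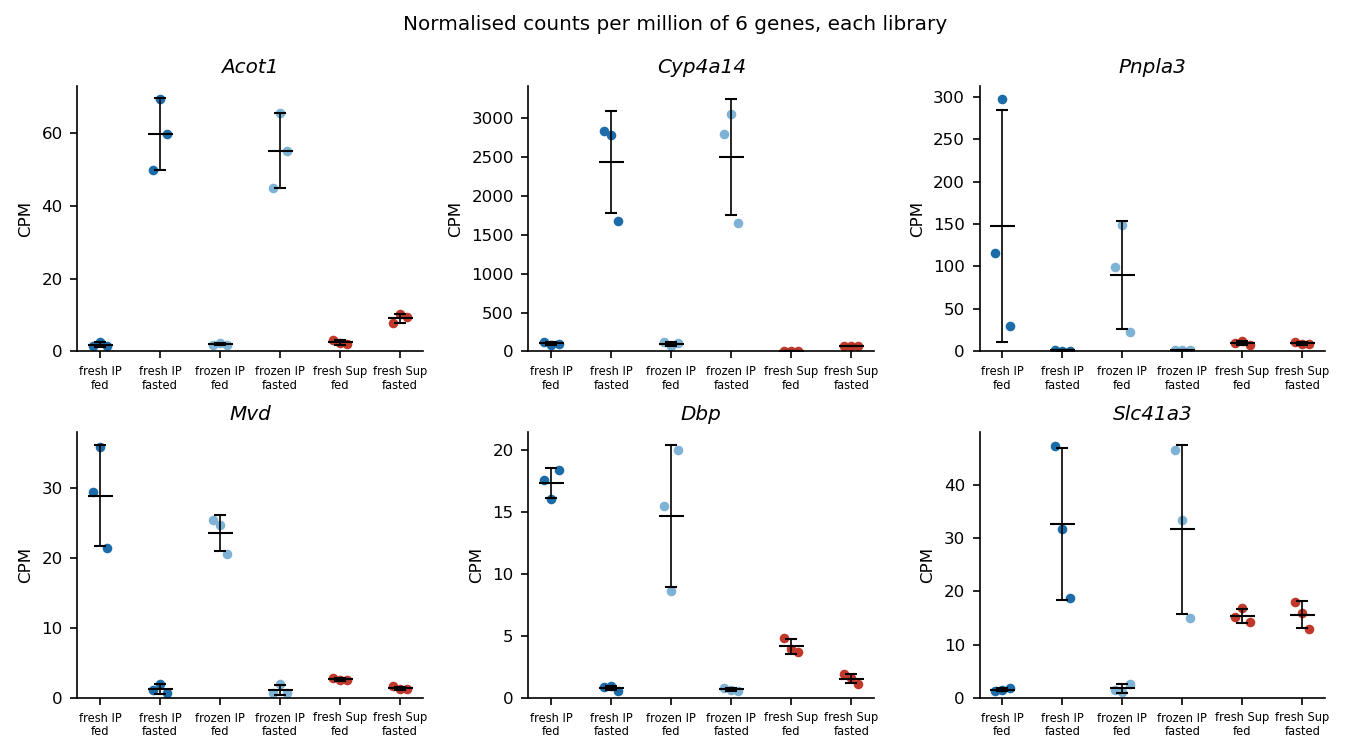
Normalised CPM (linear axes from 0) of 6 genes in each of the 18 libraries (points), with the mean and SD of each group of 3 (bars). Acot1, Cyp4a14 and Slc41a3 rise and Pnpla3, Mvd and Dbp fall with fasting in both IP preparations, and Slc41a3 and Pnpla3 did not pass the test in supernatant (0.03 ± 0.15 and -0.03 ± 0.27, log2).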

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

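The tests of library depth, a separate batch, shares within feeding states, dilution, genes chosen and measured in different mice, lists without a library, the 4-fold supernatant genes and the splits of the samples were chosen only after the results were seen.

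The fasting change differed between IP and supernatant by a test of the difference itself in 1367 genes. In log2 units, IP minus supernatant, it was 4.33 for Slc41a3, 4.17 for Cbfa2t3, 3.87 for Mtl5, 3.48 for Pmepa1, 3.37 for Tsku and 2.40 for Cd247. It was -7.32 for Chrna4, -6.96 for Pnpla3, -4.79 for Thrsp, -3.82 for Mup3, -3.67 for Scd1, -3.42 for A1bg and -2.46 for Alas2. Fat and sterol genes differed by 3.18 for Acot1, 3.12 for Acot2, 1.91 for Slc22a5, -3.53 for Mvd, -2.98 for Insig1 and -2.90 for Fdps. Signalling, clock, growth arrest and immediate early genes differed by -1.34 for Pik3r1, 1.30 for Foxo1, -0.63 for Eif4ebp2, -5.00 for Ddit4, 4.21 for Gadd45b, 3.03 for Cdkn1a, -3.04 for Dbp, -2.81 for Bhlhe41, -1.79 for Per3, 2.55 for Atf3 and -2.27 for Dusp1. Bile acid, amino acid, stress, autophagy, acute phase and xenobiotic genes differed by 1.29 for Abcb4, -1.21 for Slc27a5, -0.92 for Cyp7b1, -0.56 for Bckdha, -2.35 for Chac1, -0.69 for Xbp1, -0.64 for Pdia4, -1.31 for Fnip2, -1.69 for Itih4, -1.87 for Cyp2a5 and 1.14 for Por. Cell cycle and cell type genes differed by 3.07 for Ccne2, 2.53 for Ccne1, -1.91 for Mki67, -1.89 for Fcgr2b, -1.59 for Tie1, 1.52 for Cd68 and 1.47 for Fcer1g. For Fcgr2b, Tie1, Cd68 and Fcer1g, carry-over into the IP was not told apart from a fasting response. Of these 48 genes 19 lost the call without some library. Abcb4, Chrna4, Cyp2a5 and Eif4ebp2 lost it without fasted A of supernatant (771 calls) and Insig1 without fasted A of IP (793 calls). Atf3, Bckdha, Bhlhe41, Ccne1, Cyp7b1, Dusp1, Fnip2, Mki67, Pdia4, Por, Scd1, Slc27a5, Thrsp and Xbp1 lost it without any of several libraries.

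By camera 8 lists differed between the fractions, with adjusted p of 1.32e-07 for fatty acid oxidation, 2.5e-08 for fatty acid synthesis, 2.41e-18 for cholesterol synthesis, 1.9e-07 for the clock, 0.0213 for acute phase, 0.000804 for heat shock, 0.0213 for hepatocyte markers and 4.43e-05 for endothelial markers. With an estimated correlation the adjusted p was 0.528, 0.528, 0.46, 0.339, 0.569, 0.569, 0.696 and 0.569. Between preparations the Kupffer cell (0.00112) and stellate cell (0.00657) lists differed by camera, with adjusted p = 0.95 for both with an estimated correlation, and without fed library B of frozen IP neither was called (adjusted p = 0.533 and 0.196). Without both fed B libraries the Kupffer cell list was called (adjusted p = 3.96e-08, and adjusted p = 0.154 with an estimated correlation) and the stellate cell list was not (adjusted p = 0.236). With the mouse as a block camera called both (adjusted p = 4.65e-05 and 0.0346).

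The fasting calls in supernatant may be hepatocyte nuclei that escaped the IP, or a response or a changed share of other cells. Genes at least 4-fold higher in supernatant than in IP made up 42.4% of the 866 calls, where under 5% would fit hepatocyte RNA as the whole source, and such genes are 25.2% of all tested. This argues against hepatocyte RNA as the whole cause. The 327 genes at least 16-fold higher in IP and called there changed in supernatant by a median of 0.501 of their IP change, but choosing them by the IP call lowers this ratio, 38 passed the test of the difference, and with genes chosen and measured in different mice it ran from 0.186 to 0.849, so it decides nothing. A part from hepatocyte nuclei, cytoplasmic RNA and a response of other cell types stay open. Whether the mix of cell types in supernatant changed with fasting was not tested. The median fasting change there was 0.426 for hepatocyte, 0.402 for endothelial, -0.261 for stellate cell and -0.232 for Kupffer cell markers.

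In the fit without a block, the genes higher in frozen IP are mostly supernatant genes, 601 of 621. With the mouse as a block 1238 were higher, and how many of these are supernatant genes was not examined. Carry-over of the whole supernatant population would give every cell type a like share. The median share was 4.26% for endothelial and 0.643% for stellate markers, a ratio of 6.62 with quartiles apart. Kupffer cell (0.652%) and lymphocyte markers (0.769%) lay near the stellate ones, so the ratio rests on the endothelial list. It was 8.11 in fed and 4.90 in fasted mice, where Kupffer cell markers were lowest, shares being taken of fresh supernatant. An even carry-over of all these cell types is therefore argued against, and a larger carry-over of endothelial nuclei stays open. The depth of the shallowest frozen library (13828945 counts) is argued against as the whole cause by 587 calls without it. So is a separate batch of 1 frozen fed library, as 1 number in the labels stands apart, by 535 to 557 higher genes without any 1 of the 3. Without both fed B libraries, however, 435 genes passed, 399 of them higher. Without both fed C libraries 595 passed, 565 of them higher. A contribution of fed B therefore stays open. Low abundance is argued against by a median of -0.050 over 666 equally scarce genes not higher in supernatant, against 0.435 over 1354 that are. Binding of nuclei after freezing, free RNA and the separate handling of frozen tissue were not tested.

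In the fit without a block 58 genes were lower in frozen IP, with a median span of 14 kb against 24.5 kb over all genes tested, and with the mouse as a block 930 were, whose span was not examined. Genes higher in IP and not past the threshold were also ranked by span. The median of the shortest 598 lay at -0.159 from that of the longest 598, which goes with a bias against short genes. The bootstrap interval (-0.177 to -0.143) was drawn over genes, not mice, so it does not measure the spread between mice. Dilution by an even carry-over of supernatant RNA would raise genes that are higher in supernatant than in IP. Of the 58, 12 are such genes (median -0.395). A binomial test for 5% false calls among the 58 gave p = 2.52e-05. The 5% holds over all 679 calls, not over the lower ones alone, and an even carry-over is argued against above. The test therefore does not decide on dilution for these 12. For the other 46 dilution stays open too. The median of -0.363 over the 58 comes from genes chosen for their fall. The highest share, which rests on 1 cholangiocyte gene, allows a fall of -0.125. In mice not used to choose the genes, the fall was past that in 5 choices of 3 to 12 genes (-0.626 to -0.437). With the mouse as a block, however, the fall beyond other genes at least 4-fold higher in IP was -0.259 to -0.021 (median -0.197, 149 to 1623 genes), where -0.032 is allowed. No biological explanation beyond the tissue preparation was tested.

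Other splits of the samples bear on chance. For fasting in fresh IP (3145), frozen IP (2918), supernatant (866) and the difference between fractions (1367), 1 of 10 splits reached the real count and the highest other gave 0, and 10 splits cannot give a share under 0.05. For the difference between preparations all 10 gave 0. For frozen minus fresh IP, 1 of 100 drawn splits reached 679, with a highest other of 3. Of the 32 splits that part every pair 1 did, with a highest other of 0. These are the smallest shares that 100 and 32 splits can give, so chance is argued against but not excluded. For IP minus supernatant, 1 of 100 reached 12181, with a highest other of 4446. Of the 32 splits 1 did, with 13 others giving any call. The highest other was 1367, equal to the count of the difference between fractions. Here too chance is argued against but not excluded.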

How the results depend on the processing

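The alternatives without both libraries of fed B or of fed C, without the 20 most abundant genes and without genes higher in 1 fraction were chosen only after the result was seen. No named call reversed under any alternative run. With the fold threshold of 2 added, the counts were 1261 for fasting in fresh IP, 1274 in frozen IP, 341 in supernatant, 7773 for IP minus supernatant and 745 for the difference between fractions, by construction. DESeq2 called 1871 genes for fasting in supernatant and 2307 for the difference between fractions, and the cause was not tested. In 1 fit of all 18 libraries, fasting gave 4204 calls in fresh IP, 4366 in frozen IP and 581 in supernatant. Such a fit takes the 3 libraries of each mouse as independent, so these counts do not rest on the spread between mice alone. That fit ended 4 named calls in frozen IP, 21 in supernatant and 2 in the difference between fractions. With the mouse as a replicate block, frozen minus fresh IP had 2168 calls and the other paired counts stayed within 1.5 times, 12233 for IP minus supernatant, 1464 for the difference between fractions and 0 for that between preparations, and among named genes only Bckdha and Ccne1, both in the difference between fractions, lost a call, while some others gained one. Leaving out 1 library gave 1429 to 2643 calls for fasting in fresh IP, 1168 to 2271 in frozen IP, 197 to 624 in supernatant, 409 to 711 for frozen minus fresh IP, 12036 to 12329 for IP minus supernatant, 0 for the difference between preparations and 771 to 1485 for that between fractions, with fewer samples. Of alternatives chosen after seeing the data, leaving out both fed B libraries gave 435 and leaving out genes higher in supernatant 66 for frozen minus fresh IP, and leaving out both fed C libraries gave 840 for the difference between fractions. Lists called by camera numbered 11, 12, 13, 5, 18, 2 and 8 in the order of the comparisons (fasting in fresh IP, frozen IP and supernatant, frozen minus fresh, IP minus supernatant, between preparations, between fractions). With an estimated correlation these were 0, 0, 1, 0, 0, 0 and 0, by directional fry 6, 14, 5, 5, 23, 0 and 6, by mixed fry 21, 21, 17, 5, 23, 0 and 17, and with the replicate block 8, 17, 4 and 9 for the last 4. The correlation of fresh and frozen fasting changes was 0.984 over genes past the threshold and 0.983 over genes with a mean logCPM of at least 3, by construction of the sets. For IP minus supernatant the median of all genes was -0.075 with size factors of DESeq2 and -0.167 by the DESeq2 test, against -0.001, and leaving out small RNA genes was not run, as the table holds none. In the differences of responses between preparations and between fractions, 2-fold changes were recovered in 16.4 and 23.9% of simulated genes without a block and in 83.6 and 34.3% with one. The shares with a block come from other simulated counts, which held a mouse effect, so the 2 settings are not alike.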

Other observations

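Fed library C stood below the other 2 fed libraries of its group in several metabolic lists. In fresh IP, frozen IP and supernatant, the median log2 difference was -0.927, -0.656 and -0.502 over the gluconeogenesis list, -0.768, -0.619 and -0.601 over the urea cycle list and -1.056, -0.647 and -0.565 over fatty acid synthesis, but -0.233, 0.02 and -0.151 over fatty acid oxidation. Among fasted libraries, B lay above and C below the others in cholesterol synthesis, by 0.81 and -0.82 in fresh IP and by 0.75 and -0.64 in frozen IP, but by 0.025 and -0.07 in supernatant. Fed library B of frozen IP, the shallowest, lay 1.35 above the other fed frozen libraries in Kupffer cell markers, and its fresh counterpart 0.71 above the other fresh ones. Hepatocyte markers in supernatant of fed mice lay 0.79 higher in library B than in A and C.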
